A study of Mus musculus with 6 samples.

How the data were processed

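Total RNA from mouse placentas at E18.5 was sequenced in 6 libraries, 3 from wild-type placentas and 3 from placentas homozygous for the Ago2 allele D598A, a change in the catalytic site of the slicing endonuclease AGO2. Per the labels' protocols, RNA was isolated with TRIzol, treated with DNase and made into libraries with a stranded total RNA kit, and both ends of each fragment were sequenced. The series' design text calls the libraries small RNA, whereas the sample labels describe total RNA libraries. The values belong to long genes, and the libraries were treated as total RNA.

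The authors deposited 1 table of estimated counts per Ensembl gene ID, with a column for each library. About 35% of the values in each library were not whole numbers within a tolerance of 0.01 (34.3% in wild type 1 and 35.6% in mutant 1, the lowest and the highest share). Each of the 28535 IDs summed to at least 10 over the 6 libraries. All 12 values of 1000000 or more were multiples of 10000, so the most abundant IDs carry a rounding error. The 2 most abundant IDs, which have no symbol in the annotation used here, held equal values in all 6 libraries and together took 5.44% of all counts. Per the submitters' processing notes, the build was GRCm39 and the tools were cutadapt 4.7, STAR 2.7.11b, Subread, featureCounts 2.0.3, DESeq2 and R 3.6.0, with no role or order given. The tool that made the estimated counts, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of a gene and of an overlapping gene on the opposite strand can therefore not be told apart with certainty. Genes of multigene families, such as the prolactin, pregnancy-specific glycoprotein and alpha-globin genes, may share reads.

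The estimated counts were rounded to whole numbers. Symbols, gene types, strands, overlaps and neighbours were taken from GENCODE M21, an annotation of an earlier build than the submitters name, by matching Ensembl IDs, of which 27423 had a symbol. No coordinates are given, because the builds differ. Where several IDs shared a symbol, the ID with the highest mean kept it.

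The mutant and wild-type libraries were compared with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr defaults (a minimum count of 10 and a minimum total of 15), robust dispersion estimates and the quasi-likelihood F test, without covariates. The filter left 21997 IDs, 21372 of them with a symbol. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called changed. Levels are CPM, the counts of a gene per 1000000 counts of the library, scaled by the TMM factors, given as mean ± SD over 3 libraries. The SE of a log2 fold change was derived from the F statistic, and intervals cover 95%. The labels do not say whether the replicates of a genotype came from separate litters, so p-values measure the spread between these libraries.

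A set of 25 gene lists was fixed before the data were examined, of which 24 had at least 5 tested members and the Y-linked list had 0. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, first with the preset correlation between genes of 0.01 and then with an estimated correlation, and also with fry. Camera sets a list against all other genes. Fry asks whether the genes of a list move, on balance, in 1 direction. Named genes followed a rule fixed before the data were examined. It takes Ago2, Rtl1 and the tested members of the Dlk1-Dio3 list. It also takes the 12 largest rises and 12 largest falls among changed genes with a mean of at least 1 CPM and groups that did not overlap, leaving out unnamed models, pseudogenes and small RNA genes. From each list it takes the 3 members with the smallest p and up to 4 changed members. Other genes of a list are named where a count needs them, and these were chosen after their values were seen. After seeing the data, lists of BMP response, arterial, and venous and sinusoidal genes were added, and families of at least 8 tested genes with a shared symbol stem were tested for an excess of risen genes by a hypergeometric test, adjusted over 262 families. Changed genes within 10 Mb of Ago2 were compared with all other tested genes by a two-sided Fisher exact test.

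Counts were simulated for the 21997 tested genes, with 200 genes changed by known folds. These 200 were drawn from genes with a mean of at least 1 CPM, and counts were drawn independently for each gene. The edgeR test recovered 36% of genes changed 1.5-fold, 80% at 2-fold, 96% at 3-fold and 100% at 4-fold. Recovery at lower levels, or with variation shared between genes, was not measured. Of 170 calls in this simulation, 14 were unchanged genes (8.24%), which is above the nominal 5%. Alternatives set before the data were examined were DESeq2 1.42.0 size factors, upper-quartile factors, no low-count filter, a minimum of 1 CPM in 3 libraries, the DESeq2 Wald test, limma voom, each library left out in turn, the replicate number as a block, Y-linked expression as a covariate, and the removal of erythroid and mitochondrial genes or of genes on chromosomes X and Y. Alternatives added after seeing the data were a yolk sac or a spongiotrophoblast score as a covariate, the 4 libraries with at most 5 Y-linked reads, and wild type 1 and 2 against mutant 1 and 2.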

Results

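Mouse placental RNA was profiled at E18.5, shortly before birth, in 3 wild-type libraries and 3 libraries homozygous for the catalytic Ago2 allele D598A, to ask how the loss of AGO2 slicing changes placental gene expression, in particular that of the retrotransposon-derived gene Rtl1 and of vascular genes. The libraries held between 41919601 and 51790712 estimated counts. Replicates of a genotype differed by more than sampling noise, with a chi-square per degree of freedom of 24.2 for the closest pair, wild type 1 and 2, so no pair agreed closely enough to be the same library deposited again. This does not show that they came from separate litters. Fetal sex was not balanced. Reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 7466 in mutant 2 and 7345 in mutant 3, and to at most 5 in mutant 1 and the wild-type libraries. Xist, the RNA that silences an X chromosome in females, lay at 14.3 and 11.8 CPM in mutants 2 and 3 and between 1489 and 1975 CPM in the other libraries. The libraries also differed in tissue markers within each genotype. Afp, an abundant transcript of the yolk sac, ranged from 9.84 to 989 CPM in wild type and from 12.9 to 1718 CPM in mutants. Psg16, a spongiotrophoblast gene, ranged from 2834 to 5547 CPM in wild type and from 1158 to 6594 CPM in mutants. The first principal component held 38.9% of the variance and placed wild type 1 with mutants 1 and 2.

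**Figure D1:**
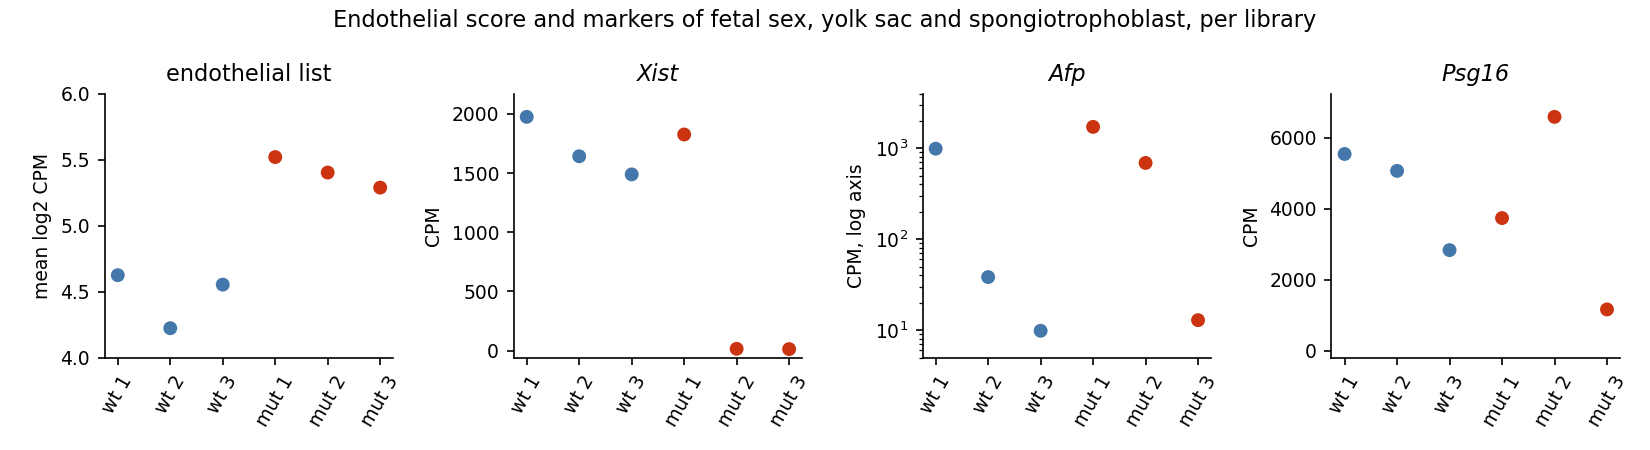
Each panel shows 1 point per library (blue, wild type; red, mutant): the mean log2 CPM of the endothelial list, and the CPM of Xist, Afp (log axis) and Psg16. The endothelial score is 4.22 to 4.62 in wild type and 5.29 to 5.52 in mutants, while Xist is low in mutants 2 and 3 and Afp and Psg16 vary within both genotypes.

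Ago2 itself (ENSMUSG00000036698, chromosome 15) was expressed at similar levels in both genotypes. Its level was 538 ± 37.0 CPM in wild type and 516 ± 37.1 CPM in mutants (SD, n = 3 each), a log2 difference of -0.062 (SE 0.093, 95% interval -0.27 to 0.15) that did not pass the edgeR test (adjusted p = 0.909). Since the allele is a point change, this level does not check the genotype labels. Rtl1 (ENSMUSG00000085925, chromosome 12), a protein-coding gene derived from a retrotransposon, rose 6.34-fold in the mutants. It was measured at 128, 86.6 and 128 CPM in the wild-type libraries and at 761, 713 and 702 CPM in the mutants. The log2 fold change was 2.66 (SE 0.16, 95% interval 2.31 to 3.02; edgeR adjusted p = 1.06e-04). The annotation places 6 microRNA genes inside Rtl1 on the opposite strand (Mir127, Mir136, Mir431, Mir432, Mir433 and Mir434), so reads of their host transcript could count towards Rtl1 if strand was not used.

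Of the 9 tested genes of the Dlk1-Dio3 imprinted locus, which holds Rtl1, 3 rose, 0 fell and 6 did not pass. With p adjusted over the list alone, 4 passed, all higher. Dlk1, a Notch ligand homologue that is paternally expressed like Rtl1, went from 173 ± 29.4 to 312 ± 32.2 CPM (log2 fold change 0.85, adjusted p = 0.0121). Wars, a tryptophan tRNA ligase gene that borders the locus, rose by 0.45 on the log2 scale (adjusted p = 0.00817). The maternally expressed noncoding RNAs did not pass, with log2 fold changes of 0.29 for Meg3 (95% interval -0.47 to 1.06), 0.24 for Rian (-0.23 to 0.72) and 0.015 for Mirg (-0.61 to 0.64). Begain (1.37, adjusted p = 0.0986), Wdr25 (-0.088) and Dio3 (0.046) did not pass either, and the group means of Begain and Dio3 were below 0.5 CPM. The list test, camera, gave an adjusted p of 3.90e-04, upward, and an adjusted p = 0.553 with an estimated correlation. The list holds Rtl1 itself and was not tested without it. The camera call alone therefore does not show a rise of the locus beyond Rtl1. The list median ranged from 0.11 without mutant 1 to 0.48 without mutant 3 or wild type 1. With Y-linked expression as a covariate Dlk1 (log2 fold change 0.99, SE 0.18, against 0.13 without it) and Wars (0.44, SE 0.10, against 0.066) kept about the same fold, but their SE grew and their calls were lost, while Rtl1 kept its call in each alternative fit. Both calls were also lost in the 4 libraries with at most 5 Y-linked reads, that of Dlk1 without mutant 1 and in wild type 1 and 2 against mutant 1 and 2, and that of Wars without wild type 2.

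**Figure D2:**
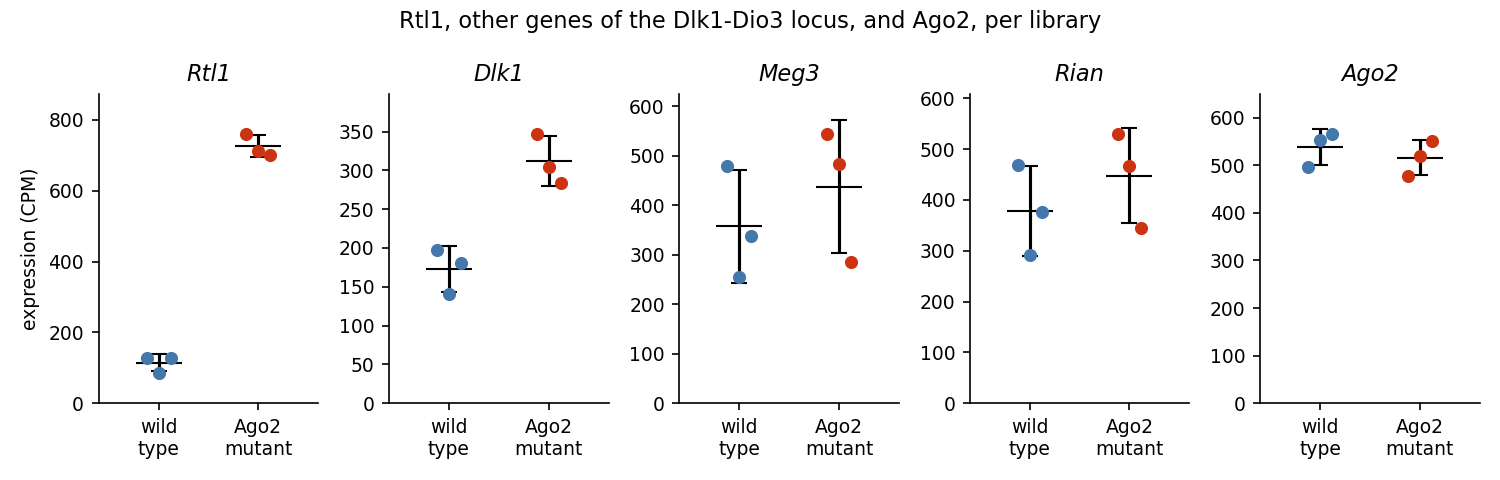
Expression in CPM of Rtl1, Dlk1, Meg3, Rian and Ago2 in each library (points; blue, wild type; red, mutant), with the mean (horizontal bar) and SD (error bar) of 3 libraries. Rtl1 lies at 702 to 761 CPM in mutants against 86.6 to 128 CPM in wild type, and the ranges of Meg3, Rian and Ago2 overlap.

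Across the transcriptome, the change was mostly upward. Of 21997 tested genes, 569 changed, of which 515 were higher and 54 lower in the mutants, and 248 rose and 18 fell by 2-fold or more. The median fold of the changed genes was 1.97 for rises and 1.65 for falls. The groups did not overlap for any of the 569 changed genes, as held for 16.9% of all tested genes, where chance gives 10%. The largest rises that the naming rule admitted were those of Chga, encoding the granule protein chromogranin A (log2 fold change 4.86, from 0.0866 ± 0.0281 to 2.56 ± 1.07 CPM, adjusted p = 9.10e-04), and Hamp, encoding the iron hormone hepcidin (4.14, from 0.403 ± 0.153 to 7.19 ± 1.16 CPM, adjusted p = 1.36e-04). The matrix protein gene Vwa1 rose from 1.79 ± 0.132 to 25.3 ± 4.5 CPM (log2 fold change 3.82, adjusted p = 3.42e-05). Fam81a (3.55), Ssu2 (3.50), the G-protein signalling regulator Rgs9 (3.32), the integrin-binding matrix gene Edil3 (3.30) and Bean1 (3.13) followed. Cd300lg, a receptor of capillary endothelium, rose from 2.67 ± 0.607 to 22.2 ± 1.94 CPM, Bmp2, a growth factor gene, from 4.72 ± 1.69 to 35.6 ± 1.66 CPM, and Bcl6b, a transcriptional repressor gene, from 1.23 ± 0.0768 to 8.25 ± 0.825 CPM. Ntrk2, the receptor of the neurotrophin BDNF, rose by 2.86 on the log2 scale.

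Falls were fewer and smaller. Fam107a fell from 3.59 ± 1.02 to 0.553 ± 0.0359 CPM (log2 fold change -2.69, adjusted p = 9.56e-04), and S100a14 from 8.21 ± 2.49 to 1.33 ± 0.418 CPM (-2.62, adjusted p = 0.00226). Thrsp, a regulator of fatty acid synthesis, fell 5.59-fold and Slc27a3, of the fatty acid transport protein family, 1.95-fold. Apela, a peptide ligand of the apelin receptor, fell 2.63-fold, from 5.59 ± 0.316 to 2.12 ± 0.561 CPM. The other named falls were Rhbdl3 (-1.67), Fibin (-1.54), the complement protease gene Masp1 (-1.19, overlapped on the opposite strand by the more abundant Rtp4), Havcr1 (-1.13), the lysophosphatidic acid receptor Lpar4 (-1.08), Scube3 (-1.03) and Gbp5 (-0.89). With Y-linked expression as a covariate 185 genes passed (184 higher and 1 lower, 184 of them shared with the 569), and of the 12 named falls Fam107a alone kept its call. Each of the 385 lost genes kept its sign. The median ratio of the log2 fold change with the covariate to that without was 1.04 over these genes and that of the SE 1.44, and over the 53 lost falls the ratios were 0.891 and 1.57. The log2 fold changes of the 11 named falls with the covariate were -2.49 for Thrsp, -2.22 for S100a14, -1.15 for Fibin, -1.06 for Lpar4, -1.02 for Apela, -0.995 for Rhbdl3, -0.95 for Havcr1, -0.79 for Gbp5, -0.78 for Scube3, -0.77 for Slc27a3 and -0.68 for Masp1. Leaving out wild type 2, wild type 3, mutant 1 or mutant 2 left 285, 333, 291 and 300 changed genes. Of the 12 falls 10 passed without wild type 1, 7 without wild type 2, 8 without wild type 3, 10 without mutant 1, 6 without mutant 2, 10 without mutant 3 and 2 in the 4 libraries with at most 5 Y-linked reads. Over 20 alternatives the call was lost in 13 for Rhbdl3 (log2 fold changes from -2.18 to -0.99), 9 for Havcr1 (-1.31 to -0.90) and 7 for Masp1 (-1.53 to -0.68). It was lost in 6 for Scube3 (-1.17 to -0.71) and 4 for Fibin (-1.79 to -1.13), and Lpar4 lost it in 4 of 19 (-1.24 to -0.92).

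Endothelial genes rose in the mutants. Of 25 list members tested, 17 were higher, 0 lower and 8 did not pass, and with p adjusted over the list alone 20 were higher and 2 lower (Tek and Vwf). Cldn5, a tight junction protein of endothelium, rose 6.59-fold, from 4.54 ± 0.818 to 29.9 ± 2.22 CPM (adjusted p = 5.06e-05). Emcn rose from 15.4 ± 2.59 to 45.7 ± 4.01 CPM, Mmrn2 from 10.4 ± 1.82 to 29.5 ± 2.07 CPM, and the progenitor and vessel antigen Cd34 2.21-fold. The rise was uneven across the list. Log2 fold changes of markers that did not pass were 0.41 for Cdh5 (VE-cadherin), 0.43 for Pecam1, 0.99 for Sox7, 0.37 for Sox17, 0.22 for Egfl7, 0.029 for Esam, -0.29 for Tek and -0.43 for Vwf. The list median was 1.01 on the log2 scale, a 2.02-fold difference. Camera gave an adjusted p of 9.09e-22, an adjusted p = 0.553 with an estimated correlation, and fry gave an adjusted p of 0.0477. With Y-linked expression as a covariate 11 of the list's genes were higher, while the median log2 fold change of the 17 changed genes was 1.35, against 1.16 without it.

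Genes of angiogenic signalling changed in part. Of 29 tested members 8 rose, 1 fell and 20 did not pass, and adjusted over the list alone 13 were higher and 4 lower. The vessel-destabilizing ligand Angpt2 rose from 13.1 ± 1.78 to 48.0 ± 7.53 CPM (log2 fold change 1.87, adjusted p = 3.60e-04), although it overlaps Mcph1 on the opposite strand (18.7 CPM). The apelin peptide gene Apln rose by 1.75 on the log2 scale (adjusted p = 1.28e-04) and its receptor Aplnr by 2.55 (adjusted p = 0.00261). Kdr, the main VEGF receptor of endothelium and a member of both lists, rose from 70.4 ± 8.06 to 158 ± 21.1 CPM. Cxcl12, Nrp1, Ephb4 and Notch1 rose as well, and Jag1 fell by 0.35 on the log2 scale (adjusted p = 0.0472). Vegfa (-0.053), Flt1 (-0.099), Pgf (0.12) and Dll4 (-0.32) did not pass. The list as a whole had a camera adjusted p of 4.37e-04, upward, and an adjusted p = 0.621 with an estimated correlation. Its median of 0.20 ranged from 0.16 without mutant 1 or wild type 2 to 0.37 without mutant 3, and was 0.30 without wild type 1.

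**Figure D3:**
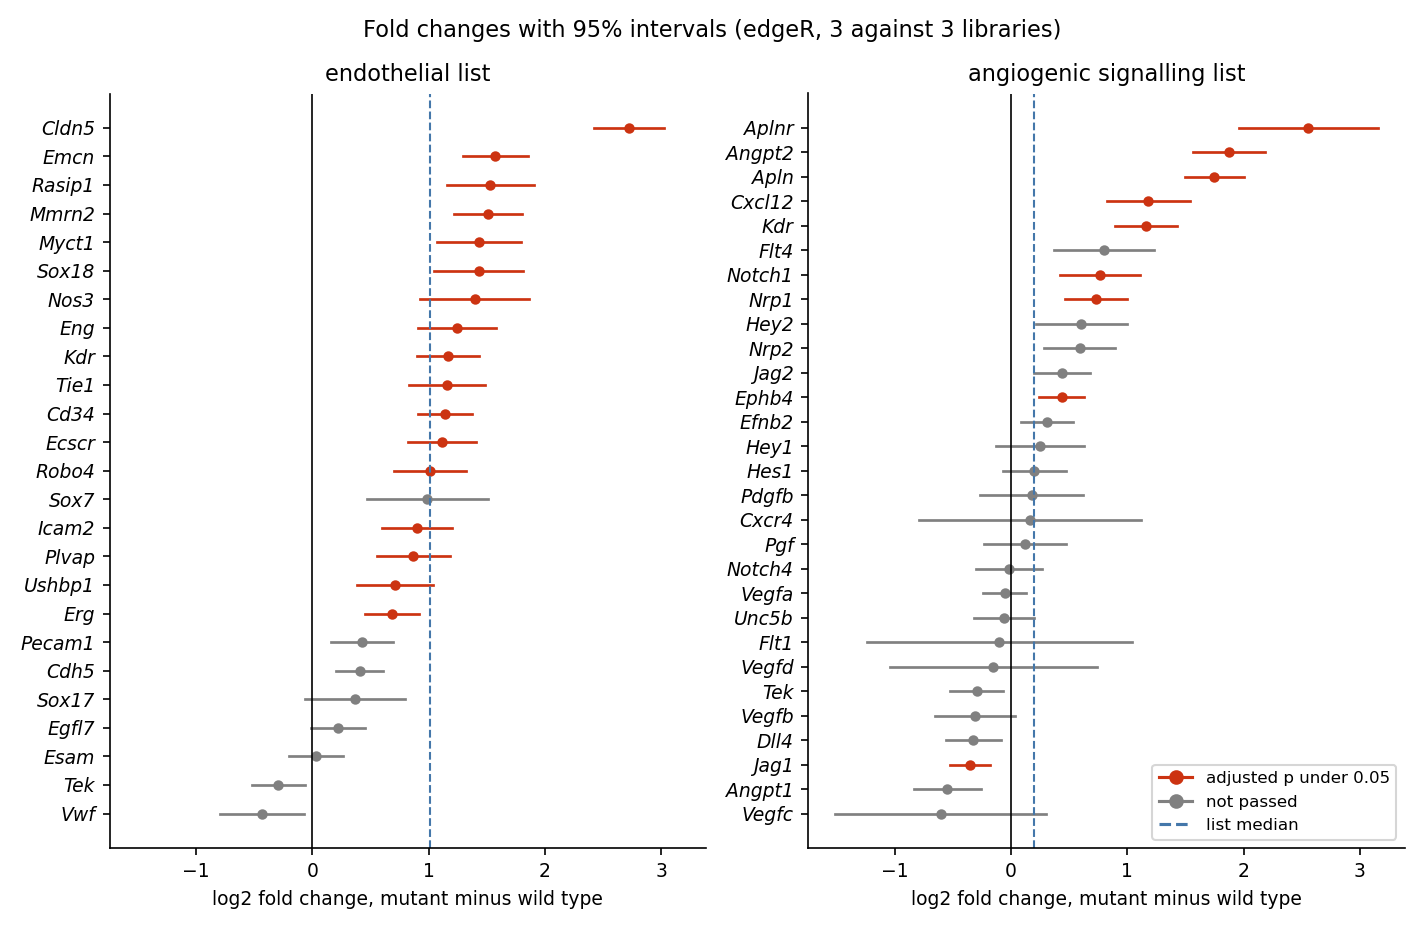
Log2 fold change (mutant minus wild type, x axis) of each tested gene of the endothelial list (left) and the angiogenic signalling list (right), with 95% intervals from edgeR. Red marks an adjusted p under 0.05, grey genes did not pass, and the dashed line is the list median, 1.01 and 0.20. Cldn5 (2.72) and Aplnr (2.55) lead the lists, and Vwf (-0.43) and Vegfc (-0.60) are at the other end.

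The pericyte, stroma, leukocyte, decidua and glycogen trophoblast lists held few changed genes. In the pericyte and smooth muscle list 1 of 16 genes rose, the adhesion molecule Mcam, which endothelium also expresses (log2 fold change 1.14, adjusted p = 0.0155). Adjusted over the list alone, 3 were higher. Tagln (0.44) and Myl9 (0.37) did not pass. For this list camera gave an adjusted p of 0.0186 and an adjusted p = 0.636 with an estimated correlation. In the stroma and matrix list 1 of 22 rose, Postn (periostin), from 43.1 ± 3.67 to 73.1 ± 3.72 CPM, and 2 were higher adjusted over the list alone. Lama4 (0.65) and Bgn (0.39) did not pass. Here camera gave an adjusted p of 0.0131 and an adjusted p = 0.836 with an estimated correlation. Both camera calls were lost with Y-linked expression as a covariate (adjusted p = 0.0559 for each), with medians of 0.30 for pericyte genes (0.22 without the covariate) and 0.24 for stroma (0.26). The stroma call was also lost without mutant 2 (median 0.026, adjusted p = 0.658), wild type 2 (0.18, adjusted p = 0.0830) or wild type 3 (0.21, adjusted p = 0.105) and with the yolk sac score (0.14, adjusted p = 0.125), and its median was 0.42 without mutant 3 and 0.39 without wild type 1. The pericyte call was lost without mutant 3 (0.29), wild type 1 (0.30) or wild type 2 (0.18), and the Mcam call in 4 of 20 alternatives (without wild type 3, with the yolk sac or the spongiotrophoblast score, and in wild type 1 and 2 against mutant 1 and 2), with log2 fold changes from 0.97 to 1.42 over all 20. In the leukocyte list 1 of 19 genes rose, also adjusted over the list alone. It was Lyve1, a hyaluronan receptor of macrophages and of lymphatic and sinusoidal endothelium, which went from 45.6 ± 6.68 to 202 ± 21.1 CPM (log2 fold change 2.15, adjusted p = 1.05e-04). S100a8 (-0.48) and Mrc1 (0.80) did not pass, and camera gave an adjusted p of 0.333, which was 0.0188 without mutant 3 (median 0.27) and 0.0432 without wild type 1 (0.24), 0.0108 with the DESeq2 Wald test and 0.00496 with the spongiotrophoblast score. The leukocyte median of 0.075 turned negative without mutant 2 (-0.032, adjusted p = 0.835) and without wild type 3 (-0.028, adjusted p = 0.910). In the decidua list 1 of 13 rose, likewise adjusted over the list alone, and it was Bmp2. Wnt4 (0.31) and Prl3c1 (-0.43) did not pass (camera adjusted p = 0.564, and 0.0282, upward, with the DESeq2 Wald test). In the glycogen trophoblast list 1 of 13 rose, also adjusted over the list alone, namely Igfbp7 (log2 fold change 0.59, adjusted p = 0.0353), which vessels also express and which overlaps Polr2b on the opposite strand. This call was lost in 9 of 20 alternatives, among them those without wild type 2, wild type 3, mutant 1 or mutant 2, with log2 fold changes from 0.48 to 0.74 over all 20. Prl6a1 (-0.26) and Plac8 (0.19) did not pass. The list median was -0.060 whereas camera pointed upward (adjusted p = 0.992), and it was 0.043 without mutant 3, -0.011 without mutant 2, -0.013 without wild type 1 and -0.026 without wild type 2.

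Some imprinted genes rose and none of those tested fell. Of 28 paternally expressed genes 4 rose, in both adjustments, including adjusted over the list alone: Rtl1, Ndn (necdin, from 8.85 ± 0.611 to 19.5 ± 1.23 CPM, adjusted p = 4.27e-04), Dlk1 and Mest (from 229 ± 37.7 to 409 ± 47.4 CPM, adjusted p = 0.0143). Their list median was 0.027 and camera gave an adjusted p of 0.0531, and it passed without mutant 1 (median 0.047, adjusted p = 0.0403), wild type 1 (0.041, adjusted p = 0.0483) or wild type 2 (0.052, adjusted p = 0.0473) and with the DESeq2 Wald test (adjusted p = 6.20e-05), limma voom (0.0336) or no low-count filter (0.0433). Without mutant 3 the median was 0.0066 (adjusted p = 0.141) and without wild type 3 it was 0.014 (adjusted p = 0.105). Of 31 maternally expressed genes 5 rose, and 6 were higher adjusted over the list alone. They were Cd81, a tetraspanin (log2 fold change 0.70), Pon3 (1.01), Asb4 (0.84), Cdkn1c, a cyclin-dependent kinase inhibitor, and Kcnq1 (1.44). The value of Kcnq1, at 1.23 CPM in wild type, is uncertain because the antisense Kcnq1ot1 was present at 765 CPM. The maternally expressed list had a camera adjusted p of 0.00573, upward, and an adjusted p = 0.553 with an estimated correlation. Its median of 0.15 was 0.056 without wild type 2, 0.078 without wild type 3 and 0.074 without mutant 1. With Y-linked expression as a covariate Mest, Cd81, Pon3 and Asb4 lost their calls with larger SEs, at log2 fold changes of 1.00, 0.79, 0.95 and 0.69. Over 20 alternatives the call of Mest was lost in 3, that of Pon3 in 4 and that of Asb4 in 6, among them those without mutant 1 (Mest and Pon3), mutant 2 (Pon3 and Asb4), wild type 2 (Asb4) and wild type 3 (Asb4). Among 15 retroelement-derived genes Rtl1 alone changed, and adjusted over the list alone 1 was higher and 1 lower. Ldoc1 (-0.40) and the syncytin gene Synb (-0.85, adjusted p = 0.226) did not pass. The list's median was -0.036 and its mean 0.075, with camera pointing down (adjusted p = 0.992). The median was 0.034 without mutant 2 and 0.052 without wild type 1. It was -0.086 without mutant 1, -0.085 without mutant 3, -0.10 without wild type 2 and -0.055 without wild type 3. The microRNA machinery held no changed gene among 15 (0 adjusted over the list alone). Dicer1 (-0.12), Tnrc6b (-0.093) and Ago3 (-0.082) had the smallest p, and camera gave an adjusted p of 0.311. The 8 targets of miR-196, miR-451 and miR-486, whose regulation or maturation involves AGO2 slicing, did not pass either (0 adjusted over the list alone). They include Hoxa7 (-0.65), Hoxc8 (0.44) and Pten (0.063), with a camera adjusted p of 0.705.

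Among stress and proliferation lists, 3 of 20 interferon-stimulated genes rose, and 5 were higher adjusted over the list alone. Ifi44 rose from 14.9 ± 1.72 to 25.8 ± 2.28 CPM, the antiviral enzyme gene Rsad2 from 104 ± 15.9 to 180 ± 12.4 CPM and Ifit3 from 23.5 ± 2.62 to 39.2 ± 4.32 CPM. Camera gave an adjusted p of 3.90e-04 and an adjusted p = 0.636 with an estimated correlation, and all 3 genes lost their calls with Y-linked expression as a covariate, at log2 fold changes of 0.72 (Ifi44), 0.70 (Rsad2) and 0.67 (Ifit3) against 0.80, 0.79 and 0.74 without it and with larger SEs, and also in the 4 libraries with at most 5 Y-linked reads. The list median of 0.18 was 0.024 without wild type 3, where the camera call was lost (adjusted p = 0.0959), 0.097 without mutant 2 and 0.32 without wild type 1. Of 15 immediate early genes 3 rose, in both adjustments, including adjusted over the list alone. These were Egr3 (log2 fold change 2.41, from 0.291 ± 0.00726 to 1.55 ± 0.461 CPM), the phosphatase gene Dusp1 (0.66, with Ergic1 on the opposite strand) and the nuclear receptor gene Nr4a1 (1.28). Dusp1 and Nr4a1 each lost the call in 7 of 20 alternatives, among them the Y-linked covariate (0.79 and 1.33) and those without wild type 2, wild type 3, mutant 1 or mutant 2. Camera gave an adjusted p of 0.00613 and an adjusted p = 0.553 with an estimated correlation, and the list median of 0.16 ranged from 0.086 without mutant 2 and 0.10 without wild type 2 to 0.27 without mutant 3 and 0.33 without wild type 1. No cell cycle gene of 24 passed over all genes, although 6 were higher adjusted over the list alone. Mcm3 (0.61, adjusted p = 0.0866), Tpx2 (0.43) and Mcm5 (0.54) had the smallest p. Camera gave an adjusted p of 0.00104, upward with a median of 0.24 (0.14 without mutant 2), and an adjusted p = 0.621 with an estimated correlation. With Y-linked expression as a covariate camera gave an adjusted p of 0.0750 at a median of 0.17. The median was 0.18 in the 4 libraries with at most 5 Y-linked reads. In the p53 and integrated stress response list 1 of 20 genes rose, Eda2r (1.12, adjusted p = 0.0231), and 2 were higher adjusted over the list alone. The Eda2r call was lost in 8 of 19 alternatives, among them the Y-linked covariate (0.75, adjusted p = 0.468) and those without wild type 1, 2 or 3, mutant 2 or mutant 3, with log2 fold changes from 0.75 to 1.27 over the 19. Chac1 (0.84) and Phlda3 (0.26) did not pass (camera adjusted p = 0.167). No gene of the 24 in the hypoxia list passed, and 1 was lower adjusted over the list alone, with Hk2 (-0.34, adjusted p = 0.0607), Pgk1 (0.34) and Bnip3 (-0.23) at the smallest p. Its median was 0.0026, with either sign when 1 library was left out (-0.023 without wild type 1 to 0.040 without wild type 3), while camera pointed down (adjusted p = 0.992).

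No trophoblast list other than the glycogen list held a changed gene, and in the syncytiotrophoblast, giant cell and spongiotrophoblast lists 0 passed adjusted over the list alone. All 17 spongiotrophoblast genes had a negative log2 fold change, with a median of -0.20, including Prl8a1 (-0.62), Ascl2 (-0.37) and Prl8a8 (-0.30). The downward camera call had an adjusted p of 0.0451, and an adjusted p = 0.836 with an estimated correlation. Without mutant 3, which held the lowest Psg16, the median was 0.17, and the call was also lost without wild type 1 (-0.048) or wild type 2 (-0.13), while the median was -0.67 without mutant 2 and -0.41 without wild type 3. It was lost as well with upper-quartile factors (median -0.23, adjusted p = 0.121), a minimum of 1 CPM (-0.20, adjusted p = 0.0803), the DESeq2 Wald test (-0.20, adjusted p = 0.200), the Y-linked covariate (-0.19, adjusted p = 0.370) and the 4 libraries with at most 5 Y-linked reads (-0.17, adjusted p = 0.158), all with medians about as large, and in wild type 1 and 2 against mutant 1 and 2 with a smaller one (-0.045, adjusted p = 0.244). In the syncytiotrophoblast list of 17, Cebpa (-0.66), Synb (-0.85) and the transferrin receptor Tfrc (-0.88, from 2231 ± 749 to 1211 ± 318 CPM, adjusted p = 0.282) did not pass (camera adjusted p = 0.108, and, downward, 0.0183 without wild type 1, 0.0188 without mutant 3, 0.0289 with the DESeq2 Wald test, 0.0446 with limma voom and 0.00745 with the spongiotrophoblast score). Its median of -0.075 changed sign without mutant 2 (0.027, adjusted p = 0.658) and without wild type 3 (0.024, adjusted p = 0.723). The median was -0.22 without mutant 3, -0.17 without wild type 1, -0.11 without wild type 2 and -0.032 without mutant 1. In the giant cell list of 13, Prl3b1 (-0.17), Hand1 (-0.088) and Ctsr (-0.11) did not pass (camera adjusted p = 0.519, and 0.0411, downward, in wild type 1 and 2 against mutant 1 and 2). Of 25 placental transport genes 0 passed, and 1 was lower adjusted over the list alone. The glucose transporter gene Slc2a3 (-0.61, adjusted p = 0.0547), Slc43a2 (-0.34) and S100g (-0.35) had the smallest p (camera adjusted p = 0.212). Among 18 erythroid genes 0 passed in either adjustment, including over the list alone, with Spta1 at 0.64, Ank1 at -0.29 and Hba-x at -1.10 (camera adjusted p = 0.209). The list median of 0.43 was 0.83 without wild type 1, where camera gave an adjusted p of 0.00140, and 0.26 without wild type 2 (adjusted p = 0.879) and 0.25 without wild type 3 (adjusted p = 0.421). The 17 yolk sac genes gave 0 calls in either adjustment, with Slc13a4 at -0.29, Apoc2 at 1.37 and Rbp4 at 1.52. Their median was 1.34 with a camera adjusted p of 0.209. The list passed, upward, without wild type 1 (median 4.28, adjusted p = 0.00334), without mutant 3 (1.93, adjusted p = 2.12e-04), with the Y-linked covariate (2.33, adjusted p = 8.95e-04), the spongiotrophoblast score (2.69, adjusted p = 8.97e-04) or the replicate block (1.67, adjusted p = 0.00111), in the 4 libraries with at most 5 Y-linked reads (2.49, adjusted p = 9.87e-05) and in wild type 1 and 2 against mutant 1 and 2 (1.38, adjusted p = 0.00597). Without mutant 1 the median was 0.023 (adjusted p = 0.933), without wild type 2 it was 0.83 (adjusted p = 0.545) and without wild type 3 it was 0.78 (adjusted p = 0.878).

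To ask whether changed genes gather around the edited gene, genes within 10 Mb of Ago2 were compared with all others. Of 261 tested genes there 7 changed (2.68%), against 557 of 21110 elsewhere (2.64%), an odds ratio of 1.02 (95% interval 0.403 to 2.14; Fisher exact test, two-sided, p = 0.846). The 7 included Kcnk9, a potassium channel gene (log2 fold change 2.21, adjusted p = 4.27e-04), and Cdc42ep1 (0.76, adjusted p = 0.00139), both chosen after their values were seen.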

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

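Tests of an even endothelial gain and of reads from the antisense transcript were chosen after the results were seen. Y-linked reads, which the low-count filter kept out of the comparison, were flagged because they lay far above the wild-type level. The 4 genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 7466 in mutant 2 and 7345 in mutant 3, against at most 5 in each wild-type library and 2 in mutant 1. Groups of 3 libraries were not searched for single outlying samples.

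The rise of endothelial genes was weighed against fetal sex, yolk sac tissue and an even gain of endothelial cells. The 17 changed genes had a median log2 fold change of 1.16, which was 1.35 with Y-linked expression as a covariate. All 17 were higher in mutant 1 than in each wild-type library, which adds no evidence, because the groups overlapped for none of the changed genes. Mutant 1 was the only mutant with at most 5 Y-linked reads, so what the covariate fit says on sex rests on that library. The fit of the 4 libraries with at most 5 Y-linked reads rests on it too, with a median of 1.36 for the 17 genes. A call lost in both fits is therefore not lost independently. Mutant 1 also held the most Afp (1718 CPM). Its score over the whole endothelial list was 5.52, against 4.22 to 4.62 in wild type. The median of the 17 genes was 1.11 with the yolk sac score as a covariate. The tables argue against yolk sac as the whole cause, and against sex only as far as 1 library can show. Of the 25 list members 14 had a 95% interval that excluded the list median, 6 above and 8 below, which argues against a rise of all endothelial markers by 1 factor. For the markers that rose, an even gain of cells is not decided by this. Markers that other cells also express would rise by less than the gain. That would not give a fall, whereas Tek and Vwf were lower with p adjusted over the list alone. An even gain by itself therefore does not account for these 2 genes. A gain of endothelial cells, even or of some kinds, or a change of expression within them, may still account for the rises. These were not told apart here.

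The rise of Rtl1 was weighed against the same even gain of endothelial cells and against reads of its antisense transcript. The lower end of the Rtl1 interval, 2.31, lay above the endothelial list median plus 1 SD (1.69), so Rtl1 rose by more than most of the list. The first is not decided by this, because list genes that other cells also express would rise by less than the gain. The bound of that test was reset after the values were seen. As first written, a log2 fold change of Rtl1 inside the range of the list would have spoken for the endothelial gain, and Cldn5 (2.72) rose as much as Rtl1 (2.66), so an endothelial programme like that of Cldn5 stays open. The upper ends of the intervals of Meg3, Rian and Mirg, taken as measures of the maternal transcript, reached at most 1.06, which argues against the second unless the antisense part changed apart from them. The loss of cleavage by AGO2 that the genotype names stays open as a hypothesis. It was not tested, because these counts do not measure cleavage, and ends of cut Rtl1 RNA would be needed. A rise in particular Rtl1-expressing cells was not tested either.

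Changed genes around Ago2 were tested as a sign of DNA carried along with the knock-in allele. The odds ratio was 1.02 with a 95% interval of 0.403 to 2.14, which leaves open both no excess and a 2-fold excess, so the explanation cannot be told apart from an even spread of changed genes.

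For chance in the grouping, the 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 569 changed genes, as 1 of the 10 splits did, and the highest other gave 345. That other split set wild type 1, mutant 1 and mutant 2, the libraries with the most Afp, against the rest, and the remaining 8 splits gave 0. For the gene lists, 3 of the 10 splits had as many calls as the 10 of the real split, and the highest other gave 11. Calls of camera at the preset correlation therefore also arise between libraries mixed over genotypes.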

How the results depend on the processing

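Alternatives with yolk sac or spongiotrophoblast scores, and those with fewer libraries chosen by Y-linked reads or spongiotrophoblast genes, were chosen after seeing the data. All 569 changed genes, where tested, kept their sign in each alternative. Rtl1 passed in each, with log2 fold changes from 2.50 to 2.78 and adjusted p up to 0.00304. Of 52 named changed genes, 26 kept the call in every alternative and 0 changed sign. Fits that changed the counts more than 1.5-fold were these, and except where stated the cause was not tested. The DESeq2 Wald test called 880 genes, 134 lower. Y-linked expression as a covariate left 185 (184 higher, 1 lower), and the 4 libraries with at most 5 Y-linked reads left 193 (190 and 3), a fit in which mutant 1, as the lone mutant, was assumed to vary like the wild-type libraries. The yolk sac score gave 966 (799 and 167) and the spongiotrophoblast score 981 (790 and 191). The replicate number as a block gave 996 (819 and 177). Deviations of same-numbered libraries correlated at 0.378, -0.082 and 0.384, where a correlation above 0.1 had been set as the sign of pairing. The libraries numbered 1 and 3 thus passed that bound, whereas wild type 2 correlated best with mutant 3 (0.211). A pairing by replicate number was therefore not settled. Leaving out 1 library gave 285 to 566 genes, 259 to 516 higher and 15 to 50 lower, with 285 without wild type 2, 291 without mutant 1, 300 without mutant 2 and 333 without wild type 3.

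Gene lists depended more on the test. The count of 10 lists went to 0 with an estimated correlation and to 1 (endothelial) with fry, and ranged from 7 to 13 in the other alternatives. List medians stay as they are in these tests. With an estimated correlation the calls of the Dlk1-Dio3 (0.29), endothelial (1.01), pericyte (0.22) and angiogenic (0.20) lists were lost, and with fry those of the Dlk1-Dio3 (0.29), pericyte (0.22) and angiogenic (0.20) lists. The pericyte call was also lost with the Y-linked covariate (median 0.30), the spongiotrophoblast score (0.24), the 4 libraries (0.29) and some left-out libraries (0.18 to 0.30). The spongiotrophoblast median reversed to 0.045 with its own score as a covariate, which removes the change by construction. It ranged from -0.67 to 0.17 with 1 library left out and reversed without mutant 3. At this depth and with 3 libraries per genotype, 36% of simulated 1.5-fold changes were recovered among genes of at least 1 CPM, so small changes were often not detectable.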

Other observations

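The BMP response, arterial and venous lists, the tests of symbol families and of a shift between endothelial kinds, and the apelin genes grouped here were chosen after seeing the data. Of the 8 tested genes with the stem Gimap, most of which encode GTPases of lymphocytes and endothelium, 4 rose. Of 262 families of at least 8 tested genes that share the stem of their symbol, Gimap alone held more risen genes than chance gives after adjustment, with 4 of 8 against 0.252 expected (hypergeometric test, adjusted p = 0.0161). That test takes the members as independent, so its p is too small if they vary together. Gimap4 rose from 5.18 to 22.7 CPM (log2 fold change 2.13, edgeR adjusted p = 1.05e-04), and Gimap6 (1.26), Gimap8 (1.25) and Gimap5 (1.28) rose as well. Gimap1 (1.06, adjusted p = 0.0513), Gimap9 (0.56), Gimap3 (-0.26) and the noncoding Gimap1os (0.16) did not pass.

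The apelin system moved in several parts. The ligand gene Apln rose 3.36-fold and the receptor gene Aplnr 5.88-fold, while the second ligand gene, Apela, fell 2.63-fold. The Aplnr call was lost in 2 of 20 alternatives, the replicate block and wild type 1 and 2 against mutant 1 and 2. Its log2 fold change was 2.34 to 2.89 over all 20. The Apela call was lost in 2, the Y-linked covariate (log2 fold change -1.02) and the 4 libraries with at most 5 Y-linked reads. Its log2 fold change was -1.63 to -1.01 over all 20.

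The rise of Bmp2 and of Hamp, which BMP signalling induces in liver, was followed by a test of whether BMP response genes rose more widely. A list of 11 such genes without Bmp2 and Hamp, none of them in a fixed list, was higher by 0.469 in mean log2 CPM (95% interval 0.202 to 0.735), and each mutant score (4.49 to 4.64) lay above each wild-type score (3.96 to 4.25). Camera gave p = 1.09e-07 at the preset correlation and p = 0.0165 with an estimated correlation. These p-values were not adjusted, unlike those of the fixed lists. Without adjustment, camera with an estimated correlation gave p = 0.0472 for the endothelial list, against an adjusted p of 0.553. The members that passed were Smad6 (0.79), Atoh8 (0.84) and Id1 (0.75), while Smad9 (0.90), Nog (0.56), Bambi (0.44), Tmem100 (0.30), Id3 (0.19), Msx2 (0.12), Id2 (0.10) and Smad7 (0.096) did not. This is consistent with a wider BMP response, as a hypothesis, but endothelium expresses several of these genes, and the rise of endothelial genes may contribute to the difference.

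A second hypothesis was that the endothelium shifted from arterial towards venous and sinusoidal kinds. Of 12 arterial genes 0 passed edgeR's test and the median log2 fold change was -0.032, with members on both sides (Hey2 0.61, Bmx 0.52, Sox17 0.37, Efnb2 0.31, Stmn2 0.16, Sema3g -0.026, Gja4 -0.039, Fbln5 -0.18, Gja5 -0.27, Dll4 -0.32, Vegfc -0.60 and Mgp -0.82). Of 11 venous and sinusoidal genes 5 rose (Lyve1, Aplnr, Oit3, Ephb4 and Stab1), while Flt4 (0.80), Clec14a (0.37), Selp (0.25), Nr2f2 (-0.14), Prox1 (-0.26) and Stab2 (-0.72) did not pass. Camera on the venous list gave p = 2.17e-05 at the preset correlation and p = 0.0708 with an estimated correlation, and on the arterial list p = 0.861 and p = 0.946. The venous minus arterial score was higher by 0.671 in the mutants over all members, which met the bound as first written. Because some of these genes had been seen to rise in the fixed lists, the test was then restricted, and over the 7 venous and 7 arterial genes of no fixed list the difference was 0.266, with the lowest mutant 0.190 above the highest wild-type library. That value lies between the bounds set for a shift (0.5) and for none (0.25), so a shift may be present but was not decided.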
